A study of Mus musculus with 15 samples.

How the data were processed

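Total RNA from mouse subventricular zone neural stem cells was labelled with biotin and hybridised to an Affymetrix mouse array of 22690 probe sets, 1 array per sample, per the labels' protocols. The labels give 3 groups of 5 samples, undifferentiated cells and cells at 12 h and 24 h without growth factors. The deposited table holds 1 processed value per probe set and array. MAS5 is the tool named in the submitters' processing notes, and its version, settings and any scaling are not given in the sources used here. The log base is not given either. It was settled from the hybridisation spike-ins bioB, bioC, bioD and cre, whose standard concentrations are 1.5, 5, 25 and 100 pM: the deposited values rose by 1.07 ± 0.0655 (SD over 15 arrays) per log10 unit of concentration, against 0.322 per log2 unit and 0.465 per natural log unit, so the deposited values were read as log10. The array medians ran from 0.287 to 0.453 on that log10 scale, so the table is neither quantile normalised nor median centred, and its offset stays unknown. The median SD between arrays was 0.0856 on the log2 scale over the probe sets of the lowest decile and 0.319 over those of a middle decile.

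Values were multiplied by 3.32 to give log2 values and used with no further normalisation and no pseudocount. The design had been written for linear or log2 values and was otherwise kept. Gene names came from the platform annotation: among 22626 probe sets other than controls, 20380 had 1 gene symbol, 691 had several and 1555 had none here, and only the first kind was used. Of these, 20351 matched the names of assembly GRCm38.p6 through their Entrez number and 0 symbols changed. For each gene the probe set with the highest mean over all arrays was taken, and genes with a mean above the 40th percentile of the other probe sets (0.512 on the log2 scale) were tested, 7909 of 12393. Among called genes with several probe sets above that level, probe sets disagreed in sign for 5 of 222 genes at 12 h, 105 of 954 at 24 h and 0 of 8 between the times. No change named under the rule for genes had probe sets of opposite sign.

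All 15 arrays entered the same limma fit (version 3.58.1, R 4.3.3) with a mean per group, moderated variances with a trend, and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The errors given are standard errors of that fit. Gene lists were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. fry asks whether the genes of a set move on balance to a side, and does not compare the set with other genes. Lists were fixed before the data were examined, as were the comparisons, the alternative settings and the rule for named genes: per comparison the 10 largest rises and falls among called genes whose groups do not overlap, leaving out unnamed symbols; the 4 members with the smallest p of each list that passed camera; and 16 marker genes chosen whatever their result, 1 of which is not reported here. Single values of arrays were compared with exact permutation tests.

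The label check compared the variance of spike-in probe sets between code suffixes under title and file codes, with 100000 shuffles. The 3 suffixes of the title codes are called A, B and C. Arrays of the same suffix in different groups deviated together from their group means (median correlation across genes 0.327 over 25 pairs, against -0.164 over 50 pairs of other suffixes), so values with the suffix as a block and within each suffix were computed as well. They are given for the counts and for some of the lists and named genes. Runs of consecutive title codes, 6 in all, served as a random block (correlation within runs 0.291).

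The fit was tested on simulated data with the real gene means and spreads and 200 changed genes among 7909. For 12 h against undifferentiated cells it called 32.3% of genes changed 1.5-fold, 83.4% of those changed 2-fold and 98.9% of those changed 4-fold, with 5.43% false calls; for 24 h the shares were 32.2%, 83.3% and 98.6%, with 4.72% false calls. The simulated noise was independent between arrays and equal in spread between groups, with no effects of suffixes, runs or single arrays. These rates therefore need not hold for the real arrays. Alternative settings changed the labels, pseudocount, filter, normalisation, probe set choice, variance model, samples, batch terms and single arrays. Alternatives chosen after seeing the data averaged or left out 12 h replicates 3 and 4, left out suffix C, added the actin 3'/5' ratio as a covariate and took runs of codes as a fixed block. Genes from probe sets with several or no symbols were not used in the comparisons.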

Results

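Gene expression was measured with an Affymetrix mouse array in neural stem cells of the adult mouse subventricular zone, a region that lines the lateral ventricles and holds stem cells that can make neurons, astrocytes and oligodendrocytes. The cells were grown as neurospheres. The 15 arrays fall into 3 groups of 5: undifferentiated cells kept in the growth factors bFGF and EGF, and cells taken 12 h or 24 h after the growth factors were removed and the cells were placed in serum on poly-D-lysine. The series asks which genes, myelin genes among them, change shortly after the onset of differentiation. Nothing in the labels says that the 5 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Loss of growth factors, serum and poly-D-lysine came together at 12 h and 24 h, so their effects cannot be told apart.

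The labels conflict. For 13 of the 15 samples the array code in the title differs from the code of the array file in the description, and for 8 of them the group would differ too. Groups are taken from the titles and sample sources. Bacterial and phage spike-in probe sets carry no mouse RNA, and 48.1% of their variance over the arrays lay between the 3 suffixes of the title codes (permutation test, one-sided p = 0.00237, 100000 shuffles), against 26.2% for the file codes (p = 0.0988). Taken apart, a split chosen after the result was seen, the 18 hybridisation probe sets followed the title codes (74.9%, permutation p = 0.00064) and the 27 poly-A probe sets followed the file codes (47.6%, p = 0.00961). The file codes, unlike the title codes, run in ascending order over the samples as listed. The file code suffixes nearly coincide with the title groups, since 1 suffix holds all 5 undifferentiated samples. Grouped by file codes, limma called 0 genes in each of the 3 comparisons, with 81, 118 and 21 genes at an unadjusted p under 0.05.

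At 12 h, 13 of 18 measured genes of DNA replication and 6 of 19 of mitosis fell, and 5 of 15 targets of SRF and YAP, 4 of 10 targets of BMP and TGF-beta and 4 of 17 astrocyte genes rose. Each of these lists had adjusted p = 0.338 with an estimated correlation. Acta2, the smooth muscle actin, rose by 3.22 ± 0.72 on the log2 scale (SE, n = 5 per group; limma adjusted p = 0.0165), a 9.31-fold increase. The log2 level of Acta2 was 2.41 in 12 h replicate 1, against 6.21 to 7.12 in the other 12 h arrays. Id4, an inhibitor of bHLH transcription factors and a BMP target, rose 5.48-fold (log2 2.45 ± 0.39, adjusted p = 0.00408). The replication licensing factor Cdt1 fell by 2.42 ± 0.71 on the log2 scale (adjusted p = 0.0477). In all, 261 genes were higher and 361 lower among 7909 tested, of which 69 and 145 changed at least 2-fold.

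Of the 18 measured genes of DNA replication and S phase, 13 fell and 5 did not pass (17 fell when adjusted over the list alone), with a median log2 change of -1.49. The list passed camera at an adjusted p of 1.74e-11 with a preset correlation, and had adjusted p = 0.338 with an estimated correlation. Mcm3 and Mcm7, subunits of the replicative helicase, fell by 1.97 ± 0.58 and 1.05 ± 0.20. The sliding clamp Pcna fell by 1.24 ± 0.27, the ribonucleotide reductase subunit Rrm1 by 1.18 ± 0.27, the helicase cofactor Cdc45 by 1.33 ± 0.31 and thymidine kinase Tk1 by 2.02 ± 0.49. Of 19 mitosis genes, 6 fell (18 when adjusted over the list alone), with a median of -1.34 and adjusted p = 0.338 with an estimated correlation. Among them, the mitotic kinase Cdk1 fell by 1.74 ± 0.46, Aurkb by 1.60 ± 0.41, Birc5 by 1.59 ± 0.41 and the kinesin Kif20a by 1.38 ± 0.36. The nucleolar list lost 2 of 14 members (6 when adjusted over the list alone), Gnl3 by 0.86 ± 0.19 and Nop56 by 0.86 ± 0.22 (adjusted p = 0.338 with an estimated correlation). Of 19 cholesterol synthesis genes, Dhcr7 and Nsdhl fell, by 0.87 ± 0.23 and 0.63 ± 0.19, and 4 fell when adjusted over the list alone (adjusted p = 0.464 with an estimated correlation), with list medians of -0.46, -0.67 and 0.31 within the title code suffixes A, B and C.

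Of 15 targets of SRF and YAP, which respond to actin tension and adhesion, 5 rose (10 when adjusted over the list alone). Myl9, a myosin light chain, rose by 2.34 ± 0.41, the YAP target Amotl2 by 0.93 ± 0.23 and the adhesion protein Vcl by 0.71 ± 0.19 (-0.10 within suffix C), and the list had adjusted p = 0.338 with an estimated correlation. Of 10 BMP and TGF-beta targets 4 rose (also 4 when adjusted over the list alone): Id4, Id3 by 1.91 ± 0.50, Hey1 by 1.23 ± 0.20 and Atoh8 by 1.03 ± 0.30 (adjusted p = 0.338 with an estimated correlation). The score of that list was -0.15 in 12 h replicate 1, below every undifferentiated array, and from 0.91 to 1.46 in the other 12 h arrays. Of 17 astrocyte genes 4 rose (5 when adjusted over the list alone): clusterin (Clu) by 1.71 ± 0.37, the water channel Aqp4 by 1.52 ± 0.44, the growth factor receptor Fgfr3 by 0.91 ± 0.24 and glutamine synthetase (Glul) by 0.69 ± 0.17. That list also had adjusted p = 0.338 with an estimated correlation. Gfap, the astrocyte intermediate filament, had a log2 difference of 2.10 ± 0.67 that did not pass (adjusted p = 0.0623, and 0.0290 with the code suffix as a block).

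Genes of myelin and of the response to growth factor (ERK) signalling did not pass as single genes at this time, apart from Phlda1, which fell by 1.42 ± 0.34. Of 14 myelin genes, 0 passed, whether adjusted over all genes or over the list alone. The myelin list had a camera adjusted p of 0.0206 (adjusted p = 0.464 with an estimated correlation), with medians of -0.25, 0.48 and 3.07 within suffixes A, B and C, the last from 1 array per group. Its score was 2.29 in 12 h replicate 5 and from -0.14 to 0.61 in the other 12 h arrays. The undifferentiated arrays lay from -0.47 to 0.67. The log2 difference was 0.82 ± 0.98 for Mbp, 0.80 ± 0.47 for Cnp, 0.76 ± 0.61 for Mag and 0.70 ± 0.56 for Sox10. Within suffix A it was -1.53 for Mbp, -0.62 for Mag and -0.83 for Sox10. The ERK-response list had a median of -1.13, with 1 of 12 members past the threshold and 6 when adjusted over the list alone (adjusted p = 0.367 with an estimated correlation), and the difference for Ccnd1 was -1.56 ± 0.59 (0.31 within suffix B). Further markers that did not pass were Nes (-0.95 ± 0.37), Egfr (-0.79 ± 0.24), Mki67 (-1.12 ± 0.39), Sox2 (0.61 ± 0.24), Pdgfra (1.20 ± 0.57), Tubb3 (0.66 ± 0.21), Dcx (0.53 ± 0.36) and Olig2 (-0.25 ± 0.29, and 0.21 and 0.08 within suffixes B and C). With the code suffix as a block several of these passed in limma: Nes (adjusted p = 0.0213), Egfr (0.0252), Mki67 (0.0239), Sox2 (0.00716), Tubb3 (0.00991), Ccnd1 (0.0356) and, as the only myelin gene, Mal (0.0346).

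Among other genes whose groups did not overlap at 12 h, the clock-controlled transcription factor Dbp rose by 2.20 ± 0.29, the ER-phagy receptor Retreg1 by 2.22 ± 0.37, secretogranin Scg2 by 1.81 ± 0.39, the matrix protein Ogn by 1.79 ± 0.28 and the sorting receptor Sorl1 by 1.78 ± 0.26. Those that fell included the Groucho corepressors Tle6, by 2.18 ± 0.21, and Tle2, by 1.82 ± 0.23, the myosin kinase Mylk, by 2.11 ± 0.18, the ligand Bmp7, by 1.81 ± 0.24, and Igfbp4, by 1.77 ± 0.45. In 8.16% of genes the groups did not overlap, where chance gives 0.794%. The 12 h arrays were uneven. Replicates 3 and 4 differed by an SD of 0.150 on the log2 scale, the closest of all pairs (the next lay at 0.277). Both were kept because their hybridisation spike-ins differed (mean log10 level 1.79 and 1.53), which does not show that their RNAs were separate. Their poly-A spike-ins were alike (0.811 and 0.874, against 1.13 to 1.20 in the other 12 h arrays). The ERK-response scores of replicates 3 and 4, -0.04 and 0.01, stayed at the undifferentiated level. Replicate 1 showed no rise of the SRF and YAP list (score -0.29) or of the BMP list (-0.15). The mean beta-actin 3'/5' ratio, a measure of RNA and labelling quality, also differed between these groups of arrays. It was 2.36 ± 0.148 at 12 h against 1.95 ± 0.238 in undifferentiated cells (SD, n = 5 each, exact permutation test, two-sided p = 0.0159, adjusted p = 0.0952 over 18 tests). Single arrays overlapped, at 2.21 in 12 h replicate 3 and 2.22 in undifferentiated replicate 3. The Gapdh 3'/5' ratio was 1.29 ± 0.0772 at 12 h against 1.19 ± 0.207 (exact permutation p = 0.341, adjusted p = 0.512).

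The title code suffix, taken as a batch, holds arrays of every group: 2, 2 and 1 of undifferentiated, 12 h and 24 h cells in suffix A, 2 of each in B, and 1, 1 and 2 in C. With it as a block 632 genes were higher and 844 lower at 12 h, and with runs of consecutive title codes as a fixed block 478 and 691. Of the 622 genes called without a block, and so picked for a change over these same arrays, 616 moved the same way within each of the 3 suffixes. With the suffix block all 19 mitosis and all 18 replication genes were lower, as were 8 of 14 nucleolar, 6 of 12 ERK-response and 5 of 19 cholesterol synthesis genes. With it 9 of 15 SRF and YAP targets and 7 of 17 astrocyte genes were higher. The S-phase list medians within suffixes A, B and C were -1.96, -0.65 and -1.87, those of the SRF and YAP list 0.81, 1.25 and 0.52, and those of the ERK-response list -1.33, 0.05 and -1.92. Quantile normalisation gave 448 higher and 487 lower and median centring 420 and 445. Without the 4 arrays of suffix C the counts were 35 higher and 35 lower, with the actin ratio as a covariate 41 and 18, and with single arrays left out from 69 higher (without 12 h replicate 2) to 356 higher (without 12 h replicate 3). With 12 h replicates 3 and 4 averaged and counted as 1 sample 319 genes were higher and 569 lower, and with both left out 752 and 1168.

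**Figure D1:**
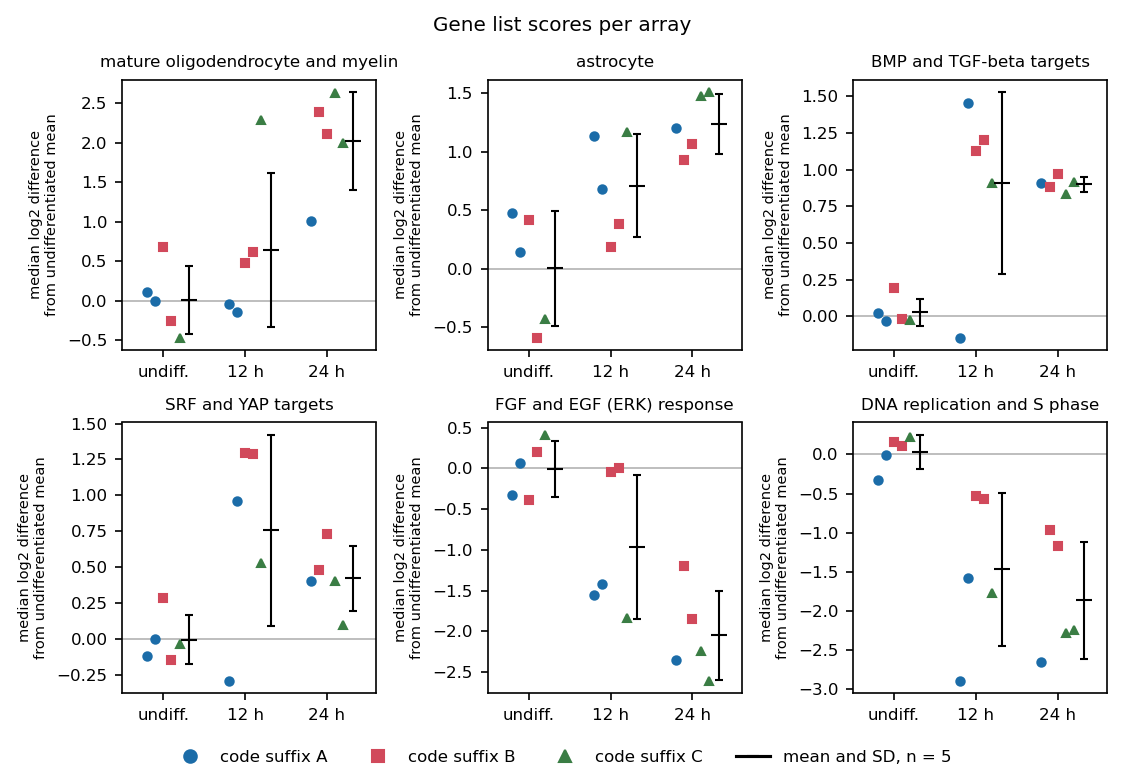
Scores of 6 gene lists on each array, as the median over the list's genes of the log2 difference from the mean of the undifferentiated arrays; symbols mark the title code suffix, and bars give the mean and SD of 5 arrays. The S-phase score lies at or below -0.53 on every 12 h array, and the ERK-response score of 12 h replicates 3 and 4 (-0.04 and 0.01) lies within the undifferentiated range.

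By 24 h, 11 of 14 myelin and 10 of 17 astrocyte genes had risen, and 10 of 12 ERK-response genes and all 18 replication and 19 mitosis genes had fallen. The 5 lists had adjusted p from 0.338 to 0.384 with an estimated correlation. Mbp, which encodes myelin basic protein, was 11.6-fold higher than in undifferentiated cells (log2 3.53 ± 0.98, SE, n = 5 per group; limma adjusted p = 0.0125). Gfap was 10.2-fold higher (3.35 ± 0.67, adjusted p = 0.00196). Dusp6, a phosphatase induced by ERK, fell by 3.87 ± 0.70 on the log2 scale (adjusted p = 0.000986). In all, 1003 genes were higher and 1533 lower, of which 310 and 493 changed at least 2-fold.

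Of 14 measured myelin genes, 11 rose and 3 did not pass (12 rose when adjusted over the list alone), with a median of 2.12. The list passed camera at 2.85e-06, with adjusted p = 0.338 with an estimated correlation. Ugt8a, which makes the myelin galactolipids, rose by 3.11 ± 0.58, the deacetylase Sirt2 by 2.63 ± 0.49, Mag by 2.36 ± 0.61, Cnp by 2.29 ± 0.47, the myelin transcription factor Myrf by 2.19 ± 0.44 and Mal by 0.87 ± 0.17. Mog lay below the expression filter and was not tested with the others. Its mean log2 levels were -0.18, 0.31 and 1.35 in undifferentiated, 12 h and 24 h cells, against a filter level of 0.51. Without the filter its difference at 24 h was 1.53 ± 0.28. Of 10 oligodendrocyte lineage genes 4 rose (also 4 when adjusted over the list alone): the transcription factor Sox10 by 2.66 ± 0.56, Bmp4 by 2.59 ± 0.61, the precursor receptor Pdgfra by 2.55 ± 0.57 and Tcf7l2 by 0.80 ± 0.22 (adjusted p = 0.338 with an estimated correlation). Olig2 had a difference of 0.06 ± 0.29 that did not pass.

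Of 17 astrocyte genes 10 rose, 2 fell and 5 did not pass, with the same counts when adjusted over the list alone. Besides Gfap, Clu rose by 2.37 ± 0.37, Aqp4 by 2.32 ± 0.44 and Glul by 1.49 ± 0.17, while Cd44 fell by 2.57 ± 0.59 and the glutamate transporter Slc1a2 by 0.45 ± 0.17 (adjusted p = 0.0509 with the code suffix as a block). The list had adjusted p = 0.381 with an estimated correlation. Of 10 BMP and TGF-beta targets 5 rose (7 when adjusted over the list alone), led by Id4 (3.52 ± 0.39), Id3 (2.09 ± 0.50), Id2 (1.46 ± 0.40) and Hey1 (1.09 ± 0.20), with adjusted p = 0.338 with an estimated correlation. Of 15 SRF and YAP targets 5 rose (also 5 when adjusted over the list alone), among them Acta2 (3.03 ± 0.72), Myl9 (1.77 ± 0.41), Amotl2 (1.54 ± 0.23) and thrombospondin Thbs1 (1.13 ± 0.34), with adjusted p = 0.428 with an estimated correlation.

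Of 12 ERK-response genes 10 fell (also 10 when adjusted over the list alone), with a median of -2.08 and adjusted p = 0.381 with an estimated correlation. The transcription factors Etv4 and Etv5 fell by 2.82 ± 0.39 and 2.64 ± 0.47, the feedback inhibitors Spry1 and Spred2 by 2.82 ± 0.67 and 2.12 ± 0.35, and cyclin D1 (Ccnd1) by 2.74 ± 0.59. All 18 replication genes and all 19 mitosis genes fell, under both adjustments, with medians of -1.89 for each list and adjusted p = 0.381 and 0.384 with an estimated correlation. Cdt1 fell by 3.01 ± 0.71, Tk1 by 2.71 ± 0.49, Cdc45 by 1.79 ± 0.31, Rrm1 by 1.53 ± 0.27 and Ccne1 by 1.34 ± 0.25. Cdk1 fell by 2.27 ± 0.46, Aurkb by 2.10 ± 0.41, Top2a by 2.06 ± 0.42, Kif20a by 1.93 ± 0.36 and Mki67 by 1.73 ± 0.39. Of 19 cholesterol synthesis genes 10 fell (14 when adjusted over the list alone), Dhcr7 by 1.31 ± 0.23, Nsdhl by 1.11 ± 0.19, Cyp51 by 1.06 ± 0.21 and Ebp by 0.97 ± 0.16 (adjusted p = 0.406 with an estimated correlation). The cholesterol synthesis list medians within suffixes A, B and C were -0.97, -0.81 and -0.012. Of 14 ribosome biogenesis genes 6 fell (9 when adjusted over the list alone and 10 with the suffix block), with Nop56 down by 0.95 ± 0.22 and Gnl3 by 0.82 ± 0.19 (adjusted p = 0.406 with an estimated correlation).

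The neural stem and progenitor list went both ways: 3 of 15 genes rose and 3 fell (4 and 4 when adjusted over the list alone, 6 and 4 with the suffix block, camera adjusted p = 0.338). Nes, the progenitor filament, fell by 2.05 ± 0.37, the Notch effector Hes1 by 1.72 ± 0.25 and Egfr by 1.08 ± 0.24, while the RNA-binding protein Msi1 rose by 1.31 ± 0.22, Prom1 by 1.03 ± 0.32 and Sox2 by 1.03 ± 0.24. Hes1, Msi1, Prom1, Cd44, Slc1a2, Foxj1 and Rsph1 were chosen after their values were seen. Of 11 neuronal genes 3 rose and 1 fell (the same counts when adjusted over the list alone; camera adjusted p = 0.599), with Dcx up by 1.69 ± 0.36 and Tubb3 by 0.67 ± 0.21. Among markers of other cell types, 0 of 15 microglial and 0 of 10 endothelial genes passed the expression filter, and 1 of 10 pericyte and fibroblast genes did (Pdgfrb, which rose by 1.97 ± 0.23 from an undifferentiated mean of -0.24, below the log2 filter level of 0.51). Of 4 ependymal genes on the array 2 did, Foxj1, with a mean level of 0.966 on the log10 scale against a filter level of 0.154, and Rsph1, which rose by 1.51 ± 0.25 and 0.34 ± 0.09. The pericyte and ependymal lists each had adjusted p = 0.338 with an estimated correlation, and 0.0685 and 0.0632 with the code suffix as a block. Of 18 matrix and adhesion genes 2 rose and 7 fell (2 and 8 when adjusted over the list alone, camera adjusted p = 0.118).

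Other large rises at 24 h were those of the calmodulin-binding Pcp4 (3.28 ± 0.60), the glutamate transporter Slc1a1 (3.25 ± 0.52), Retreg1 (3.17 ± 0.37), the ubiquitin ligase subunit Fbxo2 (3.10 ± 0.50) and the small heat shock protein Hspb8 (2.96 ± 0.60). The largest other falls were those of Igfbp4 (-3.84 ± 0.45), adrenomedullin (Adm, -3.36 ± 0.60), the matrix protein Fbln2 (-3.16 ± 0.43), Adam12 (-3.11 ± 0.51), Camk2b (-3.06 ± 0.36), the sulfotransferase Chst7 (-2.98 ± 0.25) and the hedgehog ligand Dhh (-2.83 ± 0.58). In 25.1% of genes the groups did not overlap, where chance gives 0.794%. The mean of at least 1 group also lay below the filter level for Atoh8, Dhh, Dnajb13, Entpd2, Mal, Mobp, Ogn, Rhpn2, Rsph1, Scg2, Slc1a2, Thbs1 and Tle2, so the size of their differences is less certain.

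The beta-actin 3'/5' ratio rose with these groups, from 1.95 ± 0.238 to 2.78 ± 0.365 (SD, n = 5; exact permutation test, two-sided p = 0.00794, the smallest it allows, adjusted p = 0.0714 over 18 tests), as did the poly-A spike-ins (log10 0.698 ± 0.252 to 1.05 ± 0.0883, exact p = 0.00794, adjusted p = 0.0714). The Gapdh 3'/5' ratio was 1.34 ± 0.0788 at 24 h against 1.19 ± 0.207 in undifferentiated cells (SD, n = 5, exact permutation p = 0.151, adjusted p = 0.4). With the actin ratio as a covariate only 8 genes were called higher and 5 lower. The standard errors grew by a median factor of 1.76, while the genes called without the covariate kept a median of 0.905 of their change (lower quartile 0.633). Quantile normalisation shifted the median of all genes by 0.104 and median centring by 0.138 on the log2 scale, giving 1585 higher and 1315 lower, and 1564 and 1229. The share of calls that were higher thus moved from 39.6% to 54.7% and 56.0%. With the code suffix as a block 1434 genes were higher and 1874 lower, and 2521 of the 2536 called genes, picked in the same manner, moved the same way in each suffix. The myelin list medians within suffixes A, B and C were 0.95, 2.12 and 3.12, those of the ERK-response list -2.11, -1.34 and -2.85, and those of the S-phase list -2.40, -1.18 and -2.45. Without the 4 arrays of suffix C 516 genes were higher and 612 lower.

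**Figure D2:**
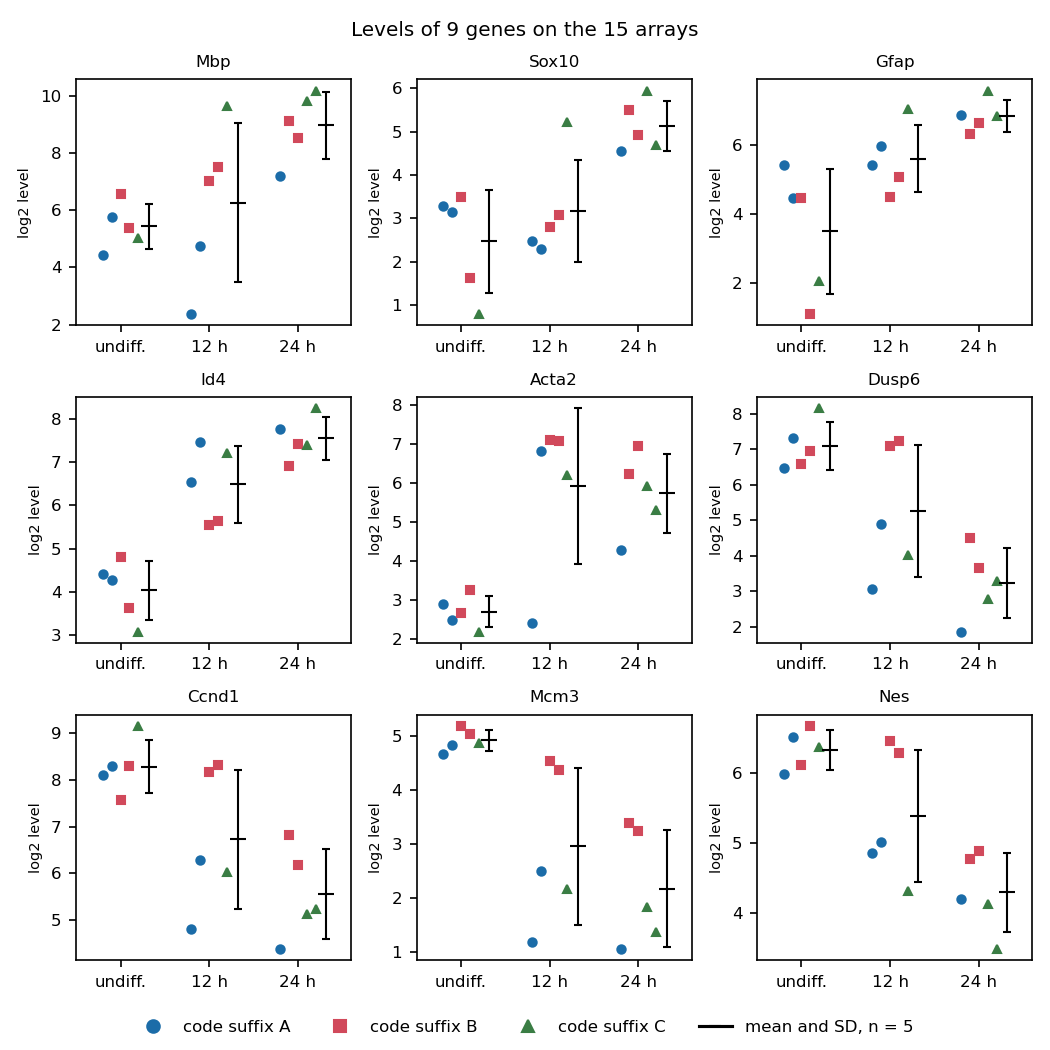
Log2 levels of 9 genes on each of the 15 arrays, by group, with symbols for the title code suffix and bars for the mean and SD of 5 arrays. Mean Mbp levels are 5.43, 6.26 and 8.97 in undifferentiated, 12 h and 24 h arrays, and mean Nes levels are 6.34, 5.39 and 4.29.

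**Figure D3:**
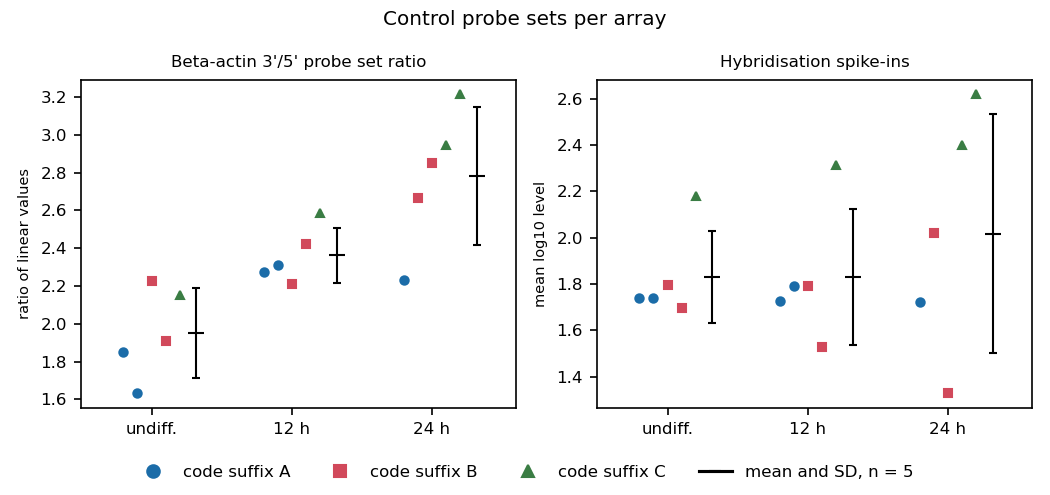
Control probe sets on each array: the ratio of the 3' to the 5' beta-actin probe sets and the mean log10 level of the hybridisation spike-ins, with bars for the mean and SD of 5 arrays. The actin ratio averages 1.95, 2.36 and 2.78 over the groups, and the spike-ins lie highest on the arrays of suffix C.

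Between 12 h and 24 h few genes passed: 5 were higher at 24 h and 28 lower (limma, adjusted p under 0.05), of which 5 and 14 changed at least 2-fold. The ectonucleotidase Entpd2 was 3.13-fold higher at 24 h (log2 1.65 ± 0.30, SE, n = 5 per group; adjusted p = 0.0330). Ctnna2 rose by 1.36 ± 0.28, Pdgfrb by 1.29 ± 0.23, Dnajb13 by 1.06 ± 0.19 and Rhpn2 by 1.05 ± 0.21. The lysosomal protease Ctsc was 3.62-fold lower (-1.86 ± 0.23, adjusted p = 0.00453), and the imprinted gene Mest fell by 1.81 ± 0.34, the protease inhibitor Timp4 by 1.79 ± 0.31, carbonic anhydrase Car2 by 1.69 ± 0.28, Igfbp2 by 1.58 ± 0.29, the caveolin Cav2 by 1.54 ± 0.30 and Chst7 by 1.51 ± 0.25.

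Of 14 myelin genes 0 passed over all genes and 10 rose when adjusted over the list alone, with a median of 1.48 and adjusted p = 0.125 with an estimated correlation. The differences were 2.71 ± 0.98 for Mbp, 2.05 ± 0.58 for Ugt8a, 1.70 ± 0.51 for Mobp and 1.58 ± 0.44 for Fa2h. Of 10 oligodendrocyte lineage genes 0 passed (2 rose when adjusted over the list alone), with 1.95 ± 0.56 for Sox10 and adjusted p = 0.0952 with an estimated correlation. The lineage list medians within suffixes A, B and C were 0.50, 0.74 and 0.07. Of 18 matrix and adhesion genes, the integrin Itgav fell by 1.06 ± 0.20, and 13 fell and 1 rose when adjusted over the list alone, with Itgb1 at -0.90 ± 0.23 (adjusted p = 0.0979 with an estimated correlation). Of 12 ERK-response genes 0 passed (5 fell when adjusted over the list alone), with Etv4 at -1.68 ± 0.39 and Spred2 at -1.36 ± 0.35 (adjusted p = 0.781 with an estimated correlation). Of 12 immediate early genes 0 passed under either adjustment, with Fos at 1.94 ± 0.78, and -0.85 within suffix C (adjusted p = 0.781 with an estimated correlation). With the code suffix as a block 1 myelin gene (Mobp, adjusted p = 0.0479) was higher, and 7 matrix and adhesion genes, Itgb1 (0.0223) among them, and 3 ERK-response genes, Etv4 (0.0129) and Spred2 (0.0235) among them, were lower. The beta-actin ratio differed here by 0.421 (exact permutation p = 0.0476, adjusted p = 0.2) and the Gapdh ratio by 0.0568 (exact permutation p = 0.286, adjusted p = 0.468).

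Of the other lists that passed camera here, astrocyte (0.044), cholesterol synthesis (0.044) and mitosis (0.0144) had 0 members past the threshold, and each had adjusted p = 0.838 with an estimated correlation. Adjusted over the list alone, 1 astrocyte gene was higher and 3 lower, and 0 cholesterol synthesis and 0 mitosis genes passed. The mitosis list medians within suffixes A, B and C were -1.35, -0.13 and -0.08. With the suffix block 2 astrocyte genes were higher and 1 lower, and 1 cholesterol synthesis gene was lower. The pericyte list, which is Pdgfrb alone (0.00488), and the ependymal list (0.0144, 0 of 2 members, but 2 higher when adjusted over the list alone) had adjusted p = 0.0952 and 0.214 with an estimated correlation.

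These counts rest on single arrays. Without 12 h replicate 3 or 4, or without 24 h replicate 1, 4 or 5, limma called 0 genes higher and 1 lower, without 24 h replicate 3 it called 0 and 8, and without 12 h replicate 5 it called 123 and 239. With 12 h replicates 3 and 4 averaged and counted as 1 sample, 0 genes were higher and 1 lower. With the code suffix as a block 40 genes were higher and 162 lower, but with runs of consecutive title codes as a fixed block 0 were higher and 2 lower. The latter shared 2 of the 33 calls. The 33 genes, picked for a change over these same arrays, moved the same way within each suffix. The myelin list medians in suffixes A, B and C were 1.02, 1.51 and 0.13, and those of the immediate early list 0.10, 1.73 and -0.86. The share of calls that were higher was 15.2%, or 28.6% after quantile normalisation and 37.0% after median centring.

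The changes at 12 h and 24 h overlapped. A total of 217 genes rose and 347 fell in both comparisons and 0 moved in opposite directions, where independent lists would share 33.1 and 70.0. Simulated arrays in which no gene changed, controls included, shared 0 and 0. With no changed genes few calls can be made, so this does not show how much of the overlap comes from the shared controls. The simulation also held no effects of the code suffixes and runs that 12 h and 24 h arrays share. With the control arrays split into 2 and 3 (20 splits) a median of 28.5 rose (2 to 129) and 38 fell (2 to 165) in both. Each comparison then has only 2 or 3 control arrays. The 33.1 and 70.0 rest on the full lists, so the split counts cannot be set against them. Across genes, which are not independent replicates, the log2 changes correlated at 0.864 (0.499 in simulated unchanged groups, and a median of 0.747, from 0.629 to 0.790, with split controls), with a covariance of 0.247 against 0.0238 simulated and a median of 0.229 with split controls.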

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

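The tests of mislabelling, of a shared RNA, of the code suffix, of quantile normalisation as the cause of the 24 h changes, and of the splits under file codes were chosen after their results were seen. A sample was singled out where its gap to the nearest of the 5 arrays of its group exceeded the 95% critical value of Dixon's test. This held in 23 of 435 groups (5.29%), and chance singles out about 1 in 20 groups. Of the 23, 14 lay at 12 h, 8 of them in replicate 1 and 5 in replicate 5.

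At 12 h, replicate 1 lay low in Acta2 (gap 0.807 of the range), Myl9 (0.840), Olig2 (0.714), Cyp51 (0.738) and the cholesterol synthesis score (0.724), and high in Egfr (0.744), the Notch score (0.810) and the interferon score (0.765). Replicate 5 lay high in Sirt2 (0.821) and Sox10 (0.736) and low in Igfbp4 (0.763), Pcp4l1 (0.805) and 18S rRNA (0.777), and replicate 2 lay high in Nsdhl (0.717). Over the genes tested, 12 h replicate 5 lay closest to 24 h replicates 4, 5 and 3. The SD of the log2 difference was 0.316, 0.345 and 0.359, against 0.404 for the closest 12 h array. The closest array to 12 h replicates 1 and 2 was also a 24 h array (0.482 and 0.349). Whether 12 h replicate 5 is a mislabelled 24 h array was not tested. At 24 h, replicate 2 lay high in Fos (0.771) and the immediate early score (0.790) and low in 18S rRNA (0.724), replicate 4 lay high in Ebp (0.806) and replicate 3 high in Cavin1 (0.720). Among undifferentiated arrays, replicate 5 lay high in the hybridisation spike-ins (0.792) and in Hes1 (0.727), replicate 3 high in the BMP score (0.747) and replicate 4 low in Dnajb13 (0.769). The change from undifferentiated cells differed between 12 h and 24 h for 33 genes in limma's test of that difference. Of the 691 probe sets with several gene symbols and the 1555 with none, 1019 lay above the filter level. They were left out of all gene counts, and in a limma fit of their own 37 passed at 12 h, 226 at 24 h and 4 between the times.

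Replicate 1 of 12 h showed no rise of the SRF and YAP list (score -0.29) or of the BMP list (-0.15). Its S-phase score of -2.90, against -0.33 for the lowest undifferentiated array, argues against a mislabelled undifferentiated array. Array scale is argued against by its SRF and YAP score after quantile normalisation, -0.23 against 0.70 for the lowest other 12 h array. No biological explanation was tested.

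Replicates 3 and 4 of 12 h kept the ERK-response list near the undifferentiated level. Their SRF and YAP scores, the lower at 1.29 against 0.29 for the highest undifferentiated array, argue against mislabelled undifferentiated arrays. The SD of their log2 difference, 0.150 against 0.277 for the next closest pair, leaves open that a single RNA was put on both arrays, which cannot be told apart from closely matched cultures. A difference between code suffixes may contribute: the 24 h arrays of the same suffix also had smaller ERK-response falls, the lowest score at -1.85 against -2.24 for the highest of the others, a gap of 0.39. Whether that suffix marks separate cultures or array handling stays open.

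The 24 h changes went with a higher actin 3'/5' ratio. With that ratio as a covariate the 2536 called genes kept a median of 0.905 of their change (lower quartile 0.633). The share kept cannot decide whether RNA quality was the whole cause. The ratio did not overlap between these groups, with 2.22 in undifferentiated replicate 3 the highest and 2.23 in 24 h replicate 1 the lowest. The adjusted change therefore rests on slopes within groups. The calls fell to 8 higher and 5 lower, and standard errors grew 1.76-fold. The ratio moves with the groups, so a contribution of RNA quality, whole or partial, may remain. Under quantile normalisation the called genes kept a median of 0.903 (lower quartile 0.797), which argues against array scale as the whole cause. Differentiation stays among the open explanations. In this design it cannot be told apart from the loss of growth factors, the serum and the poly-D-lysine as such.

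Chance as the source of the counts was examined with 100 of the 126 splits of each 10 arrays, drawn without regard to the code suffixes and runs of codes that arrays of different groups share. As many genes as the 622 called at 12 h came from 1 split, the real one (highest other 149), and as many as the 2536 at 24 h from 1 split (highest other 3). This argues against an arbitrary division of these arrays as the source of either count. The splits treat the arrays as independent, so they cannot exclude a chance difference between a few cultures or preparations. Between 12 h and 24 h 2 of 100 splits gave 33 genes or more, the real one among them, and the same limit holds. The other split called 83 genes and put the 4 arrays of suffix B with 12 h replicate 1, a structure of the samples. With the suffix as a block 40 genes were higher and 162 lower, but with runs of codes as a fixed block 0 were higher and 2 lower, and leaving out 12 h replicate 3 or 4 or 24 h replicate 1, 4 or 5 gave 0 and 1, so the count of 33 is not settled. Under the file codes limma called 0 genes, with 81, 118 and 21 at an unadjusted p under 0.05. Any split equals a count of 0 (100 of 100 in each comparison), so these splits say nothing about chance. Their highest others called 1227, 1894 and 1485 genes, a structure of the samples, and each put all of its arrays titled undifferentiated on the same side.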

How the results depend on the processing

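Averaging or leaving out 12 h replicates 3 and 4, leaving out suffix C, the actin ratio as a covariate and runs of codes as a fixed block were chosen after seeing the data. The cause of the differences below was not tested, except that leaving out arrays or using only the 2 groups lowers the number of samples. Counts are given as genes higher and lower. Under the file codes limma called 0 and 0 genes in every comparison, with 81, 118 and 21 at an unadjusted p under 0.05. At 12 h the counts of 261 and 361 became 448 and 487 with quantile normalisation, 420 and 445 with median centring, 168 and 236 with only the 2 groups, 632 and 844 with the code suffix as a block, 633 and 825 with runs of codes as a random block and 478 and 691 with runs as a fixed block. They became 319 and 569 with replicates 3 and 4 averaged, 752 and 1168 with both left out, 35 and 35 without suffix C and 41 and 18 with the actin ratio. Leaving out single arrays gave 69 to 356 higher and 103 to 649 lower. The arrays that moved a count by over 1.5 times were undifferentiated replicates 2 (147 and 189), 4 (112 and 136) and 5 (99 and 131) and 12 h replicates 1 (240 and 222), 2 (69 and 105), 3 (356 and 649) and 5 (106 and 103). At 24 h the counts of 1003 and 1533 became 1585 and 1315 with quantile normalisation, 1564 and 1229 with median centring, 1557 and 1920 with array weights, whose estimation stopped before it converged, 516 and 612 without suffix C and 8 and 5 with the actin ratio, and leaving out single arrays gave 776 to 1110 and 1211 to 1694. Between the times the counts of 5 and 28 became 8 and 27 with a pseudocount at the 5th percentile, 9 and 18 without a filter, 1 and 25 with a filter at the 60th percentile, 14 and 35 with quantile normalisation, 10 and 17 with median centring, 2 and 16 with the mean of all probe sets, 3 and 22 with all probe sets tested, 3 and 23 without a variance trend and 258 and 391 with array weights. They became 0 and 2 with only the 2 groups, 40 and 162 with the suffix block, 49 and 186 with runs as a random block, 0 and 2 with runs as a fixed block, 25 and 27 without suffix C, 0 and 1 with the actin ratio and 0 and 1 with 12 h replicates 3 and 4 averaged or left out. Leaving out single arrays gave 0 to 123 higher and 1 to 239 lower: without undifferentiated replicates 2 and 4 the counts were 2 and 8, and 3 and 16, without 12 h replicates 1, 2, 3, 4 and 5 they were 7 and 49, 5 and 15, 0 and 1, 0 and 1, and 123 and 239, and without 24 h replicates 1 to 5 they were 0 and 1, 4 and 6, 0 and 8, 0 and 1, and 0 and 1. The overlap of 217 and 347 genes fell to medians of 28.5 and 38 with split controls, where each comparison has only 2 or 3 control arrays.

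Signs of called genes and of lists turned mainly under the file codes, where at 12 h the log2 differences were -0.21 for Retreg1, -0.21 for Clu, -0.52 for Scg2, -0.078 for Ogn, -0.037 for Sorl1, -0.60 for Islr, -0.10 for Amotl2, -0.17 for Glul, -0.33 for Fgfr3, 0.066 for Mcm7, 0.086 for Pcna, 0.16 for Tle6, 0.10 for Mylk, 0.29 for Tle2, 0.13 for Dhcr7 and 0.086 for Nsdhl. At 24 h they were -0.48 for Pdgfra, -0.081 for Gfap, 0.19 for Spry1, 0.072 for Gnl3, -0.22 for Tubb3, -0.26 for Prom1 and -0.67 for Igfbp5. List medians under the file codes were -0.18 (astrocyte), 0.17 (cholesterol synthesis) and 0.017 (SRF and YAP) at 12 h, -0.086 (astrocyte), -0.16 (ERK response) and 0.056 (ribosome biogenesis) at 24 h and -0.091 (ERK response) between the times, where camera's direction turned even if the median did not. Other turns of these were the 12 h myelin list with the actin ratio (median 0.12, camera direction down), the 24 h pericyte list without a filter (-0.042), and within suffixes the 12 h myelin list (-0.25 in A), the 12 h ERK-response list (0.047 in B), Vcl (-0.10 in C), the 12 h cholesterol list (0.31 in C) and the immediate early list between the times (-0.86 in C). Of the genes named without passing, signs turned within suffixes for Mbp (-1.53), Sox10 (-0.83) and Mag (-0.62) in A, Ccnd1 (0.31) in B and Olig2 (0.21 in B, 0.08 in C) at 12 h, for Olig2 (-0.39 in A) at 24 h and for Fos (-0.85 in C) between the times. Low signal limits markers near the filter level of 0.51 on the log2 scale. The labels give no replicate numbers to pair by, so pairing across groups was fitted only through runs of consecutive title codes, as given above.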

Other observations

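The families below were picked by name after the values were seen, and 18 families were tested with camera per comparison. Insulin-like growth factor binding proteins, which hold IGF outside cells, split at 24 h, with 2 of 5 members higher and 3 lower (adjusted p = 0.392). Igfbp4 fell by 3.84 ± 0.45 (SE, n = 5 per group, limma adjusted p = 8.51e-05), Igfbp3 by 2.68 ± 0.70 and Igfbp2 by 1.74 ± 0.29 on the log2 scale, while Igfbp5 rose by 1.26 ± 0.47. Of 6 genes of the TLE (Groucho) family, taken by name, 2 fell at 12 h (camera adjusted p = 0.0386, and adjusted p = 0.324 with an estimated correlation). At 24 h 3 of them fell, Tle6 by 2.58 ± 0.21, Tle2 by 2.39 ± 0.23 and Tle5 by 1.42 ± 0.33 (family adjusted p = 0.31). The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose by 2.21 ± 0.51 and 2.26 ± 0.48 at 24 h, and by 1.48 and 1.84 after quantile normalisation (2 of 3 members, family adjusted p = 0.053).

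Of 4 genes of caveolae, the membrane pits coated by caveolins and cavins, Cav1 rose by 2.39 ± 0.60 at 12 h and the others did not pass (family adjusted p = 0.0508, and adjusted p = 0.515 with an estimated correlation). Between 12 h and 24 h 1 of the 4 fell, Cav2 by 1.54 ± 0.30, and the differences of Cav1 and Cavin1, -1.72 ± 0.60 and -1.30 ± 0.46, did not pass (family adjusted p = 0.00162, and adjusted p = 0.382 with an estimated correlation). Of 3 small heat shock proteins, which hold unfolded proteins in solution, Hspb8 and Hspb1 rose at 12 h, by 2.49 ± 0.60 and 0.58 ± 0.13 (family adjusted p = 0.0185, and adjusted p = 0.324 with an estimated correlation). At 24 h Hspb8 and Cryab rose, by 2.96 ± 0.60 and 1.39 ± 0.33 (family adjusted p = 0.188). Of 40 cytosolic ribosomal protein genes 1 fell at 24 h, and their median difference was 0.30 as deposited but -0.07 after quantile normalisation (family adjusted p = 0.0477, and adjusted p = 0.889 with an estimated correlation).

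Of the lists fixed before the data were examined, several did not pass camera at 24 h. The fatty acid and sphingolipid list had 4 of 16 members higher and 3 lower (camera adjusted p = 0.409), the unfolded protein list 3 of 18 higher and 2 lower (0.422), the glycolysis and hypoxia list 2 of 15 higher and 3 lower (0.756), the Notch list 1 of 10 higher and 2 lower (0.741), the interferon list 1 of 7 higher and 2 lower (0.984), the Wnt feedback list 1 of 3 higher (0.96), the inflammation list 0 of 3 (0.247), the p53 list 4 of 12 lower (0.118) and the immediate early list 1 of 12 lower (0.984). With the code suffix as a block these counts moved by at most 2 genes in a direction. The p53 list, with 1 higher and 6 lower when adjusted over the list alone, had medians of -0.35, -0.39 and -0.59 within suffixes A, B and C. By fry it moved on balance to a side (median -0.45, fry adjusted p = 0.0164), as did the inflammation list (median 0.56, fry adjusted p = 0.0265) and the matrix and adhesion list (median -0.70, fry adjusted p = 0.0176, camera adjusted p = 0.118). The lists that passed camera were mixed by fry. At 12 h the replication, mitosis, nucleolar, SRF and YAP, BMP and astrocyte lists had fry adjusted p from 0.0339 to 0.0437. The ERK-response, cholesterol and myelin lists had 0.0524, 0.121 and 0.18. At 24 h all had 0.000126 to 0.0112, apart from the SRF and YAP list (0.0812). Between the times the myelin, lineage, matrix, pericyte and ependymal lists had 0.00527 to 0.0443, and the others 0.255 to 0.568.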
